A study of Mus musculus with 12 samples.

How the data were processed

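RNA was taken from the corneal endothelium of Col8a2 Q455K homozygous and wild-type mice and sequenced as paired-end reads, with 3 biological replicates in each of 4 groups. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a kit that keeps the strand of the transcript. The submitters' processing notes name fastp, HISAT2, HTSeq, DESeq2 and the mouse build GRCm39, with no versions, and the annotation, the strand setting of the counting and any adjustment between batches are not given in the sources used here. The authors deposited whole-number read counts per gene for the 12 libraries. The authors also deposited FPKM values, which were used only to recover the gene length they imply, and tables of their own early and late comparisons with fold changes as a ratio, log2 fold changes, p-values and q-values, per the file headers. Whether the counts were adjusted between the stages before deposit is not given in the sources used here.

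The table held 32761 genes with at least 1 count in some library. Total counts ran from 19722598 to 39431676, at which 3 counts correspond to 0.076 to 0.152 CPM. Averaged over genes with enough reads to compare, the variance between replicates was 54.6 to 273.6 times the sampling noise, so replicates were not copies of each other. This average weighs abundant genes most and does not speak for genes near the level of 3 counts. Groups, batches and replicate numbers were taken from the labels. Early libraries are batch 1 and late libraries batch 2. Gene symbols were used as given, and 31474 genes matched the mouse reference gene table by their Entrez identifier. That table is of another build than the one the submitters name, so it was used for names and neighbours alone and no coordinates are given. GC content of the reference transcripts was known for 87.1% of the genes tested.

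The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr on the 4 groups, robust dispersions and the quasi-likelihood F test, in 1 fit of all 12 libraries with 8 residual degrees of freedom. Contrasts were the genotype effect early and late, their difference, and late against early within each genotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter removed 14796 genes and left 17965, and the common biological coefficient of variation was 0.464. Standard errors of log2 fold changes were derived from the F statistic. Group levels are CPM after TMM scaling, as mean ± SD. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it (limma 3.58.1), and 44 lists with at least 5 tested genes were kept. GO and KEGG terms of 10 to 500 tested genes, carried by the deposited tables, were tested by a one-sided Fisher's exact test against the tested genes with a term.

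The genes named were chosen by a rule fixed before the data were examined. For each genotype effect it takes the 10 highest and 10 lowest log2 fold changes among genes past the threshold, with a gene symbol that is not a clone or model name, at least 5 CPM in the higher group and no overlap between genotypes. For the interaction, with no rule on overlap, and for the stage comparisons it takes up to 5 in each direction, and for terms the 5 with the smallest p per direction. A fixed panel is given whatever its p, apart from a gene not reported here, and up to 4 members with the smallest p stand for each list. Genes outside the rule are named as the few members of a small count or to weigh an explanation, after their values were seen.

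Counts were simulated for 17965 genes with the real means, library sizes and dispersions, and the changed genes were drawn from those of at least 5 CPM. For the early comparison 13 of 100 genes changed 2-fold and 92 of 100 changed 4-fold were recovered, with 3 false calls among the unchanged genes. For the late comparison 13 and 91 of 100 were recovered, with 7 false calls. A count of calls therefore misses most 2-fold changes. Run by stage on protein-coding genes, DESeq2 1.42.0 gave log2 fold changes within 0.01 of the authors' for 99.9% of genes early and 100% late.

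The alternatives tried were DESeq2 size factors, no filter and a stricter filter of 5 CPM in 3 libraries, DESeq2's Wald test, limma-voom with sample weights, fits of the compared libraries alone, a replicate block, protein-coding genes alone, an estimated list correlation and leaving out each library. Offsets for gene length and for GC content, and leaving out early wild-type replicate 2 and late wild-type replicate 1 together, were chosen after seeing the data. Same-numbered replicates did not deviate together (correlations from -0.09 to 0.08 between genotypes), so the numbers were not taken to pair animals. Stage adjustment was simulated with ComBat_seq (sva 3.50.0).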

Results

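Messenger RNA of the corneal endothelium, the cell layer that lines the back of the cornea and pumps fluid out of it, was sequenced from mice homozygous for the Q455K change in Col8a2 and from wild-type mice. Col8a2 encodes a collagen VIII chain of Descemet membrane, the basement membrane of this layer, and the change models early-onset Fuchs endothelial corneal dystrophy. The 12 libraries formed 4 groups of 3 biological replicates, mutant and wild type at an early stage (up to 2 months of age) and at a late stage (from 8 months). All early libraries belonged to batch 1 and all late libraries to batch 2, so age and batch cannot be told apart in any comparison between stages. Total counts ran from 19722598 in early wild-type replicate 2 to 39431676 in early mutant replicate 1. Of 32761 genes in the count table, 17965 passed the low-count filter and were tested. Every library held both Xist (78.3 to 185 CPM) and Y-linked transcripts (31.3 to 67.7 CPM), and how many animals went into a library is not given in the sources used here.

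Col8a2 itself was abundant in every library, and its level did not differ between genotypes beyond the replicate spread. Early mutants held 938 ± 122 CPM (SD, n = 3) against 1180 ± 568 in wild type, a log2 fold change of -0.32 ± 0.32 (SE, adjusted p = 0.71). Late mutants held 889 ± 150 CPM against 938 ± 235, a log2 fold change of -0.08 ± 0.32 (adjusted p = 0.9). The allele changes 1 amino acid, so the level of the transcript does not check the genotype labels. Col8a1, the partner chain, was at 1540 ± 591 CPM in early mutants against 1060 ± 275 (adjusted p = 0.61). The transport gene Slc4a11 was 1.48-fold higher in early mutants without passing the threshold (adjusted p = 0.62).

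The early comparison asked what differs between mutant and wild-type endothelium before the late stage. Genes of macrophages and of the complement system, immediate early genes, matrix-remodelling genes and stress-response genes were higher in early mutants, and few genes were lower. Ctss, a lysosomal protease of antigen-presenting cells, rose 14.2-fold (69.6 ± 29.3 against 4.91 ± 2.2 CPM), and C1qa and C1qc, subunits of the first complement component, rose 19.8-fold and 12.7-fold. Egr1, an immediate early transcription factor, rose 10.5-fold, from 4.66 ± 3.16 to 48.7 ± 22 CPM. Hmox1, the heme-degrading enzyme of the oxidative stress response, rose 3.74-fold (adjusted p = 0.00071), and Hspa5, the main chaperone of the endoplasmic reticulum, rose 2.21-fold (248 ± 24.7 to 549 ± 33.1 CPM), a call lost in 7 of 23 alternatives, among them leaving out any 1 early library.

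Of the genes selected by size, Ctla2a had the highest early fold, 53.4-fold, from 0.332 ± 0.203 to 17.9 ± 8.05 CPM (log2 fold change 5.74 ± 0.5 SE, adjusted p = 8.6e-06). Reads of Ctla2a may be shared with its close paralog, so its level is uncertain. Elobl followed at 48.1-fold with a wide spread (21.5 ± 20.3 against 0.48 ± 0.69 CPM). Cgref1 was 14.2-fold higher, Fxyd5, a regulator of the sodium pump and of cell adhesion, 11.8-fold, and the cyclin gene Ccnd1 10.9-fold. Pde6b, a phosphodiesterase of rod photoreceptors, was 12.3-fold higher. Only 4 genes passed the same rule in the lower direction. Lrp1b, a lipoprotein receptor family member, was 3.63-fold lower, Vwde 2.94-fold lower and Kynu, an enzyme of tryptophan breakdown, 2.94-fold lower (12.4 ± 5.14 against 36.5 ± 12.5 CPM). Tnfsf13os was 4.14-fold lower; it is antisense to another gene and the strand setting of the counting is not given in the sources used here, so its level is uncertain. Several of these calls rest on few libraries. Elobl, Vwde and Kynu lost theirs in 8 of 23 alternatives each, Lrp1b and Pde6b in 5 and Cgref1 in 4, mostly when 1 library was left out. The log2 fold change of Elobl was 4.58 without early mutant replicate 2 and 7.85 without early wild-type replicate 2, against 5.59 with all. Those of Cgref1 were 4.72 without early wild-type replicate 2 and 3.2 without replicate 3, and those of Ccnd1 were 2.71 without early mutant replicate 2 and 4.09 without early wild-type replicate 3. Fxyd5 was at 4.2 without early wild-type replicate 1, C1qc and Egr1 at 4.29 and 4.09 without early wild-type replicate 2, and C1qa at 3.26 without early mutant replicate 1. Of the fixed panel, Ptgs2, the inducible prostaglandin synthase, also rose (3.11-fold, adjusted p = 0.012). Cdkn1a was at 73.3 ± 52.3 against 23.7 ± 13.3 CPM (adjusted p = 0.22) and Ddit3 at 102 ± 17.6 against 65.5 ± 16 CPM (adjusted p = 0.51). Fn1, Tcf4, Zeb1, Tjp1, Cdh2, Nqo1 and Atp1b1 did not pass the threshold early (adjusted p from 0.57 to 0.98), and Dram1 lay near the level of 3 counts in both groups.

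By edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 100 genes were higher and 6 lower in early mutants, all by at least 2-fold. In 105 of the 106 the mutant and wild-type libraries did not overlap, which the call itself favours; among all tested genes 21.9% did not overlap, where chance gives 10%. The median gene lay at -0.11 on the log2 scale. The count was 237 by DESeq2's Wald test and 361 with no low-count filter, 51 without early mutant replicate 1, 70 without early mutant replicate 2 and 68 without early wild-type replicate 1. It was 179 without late wild-type replicate 1, which is outside this comparison but in the same fit.

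**Figure D1:**
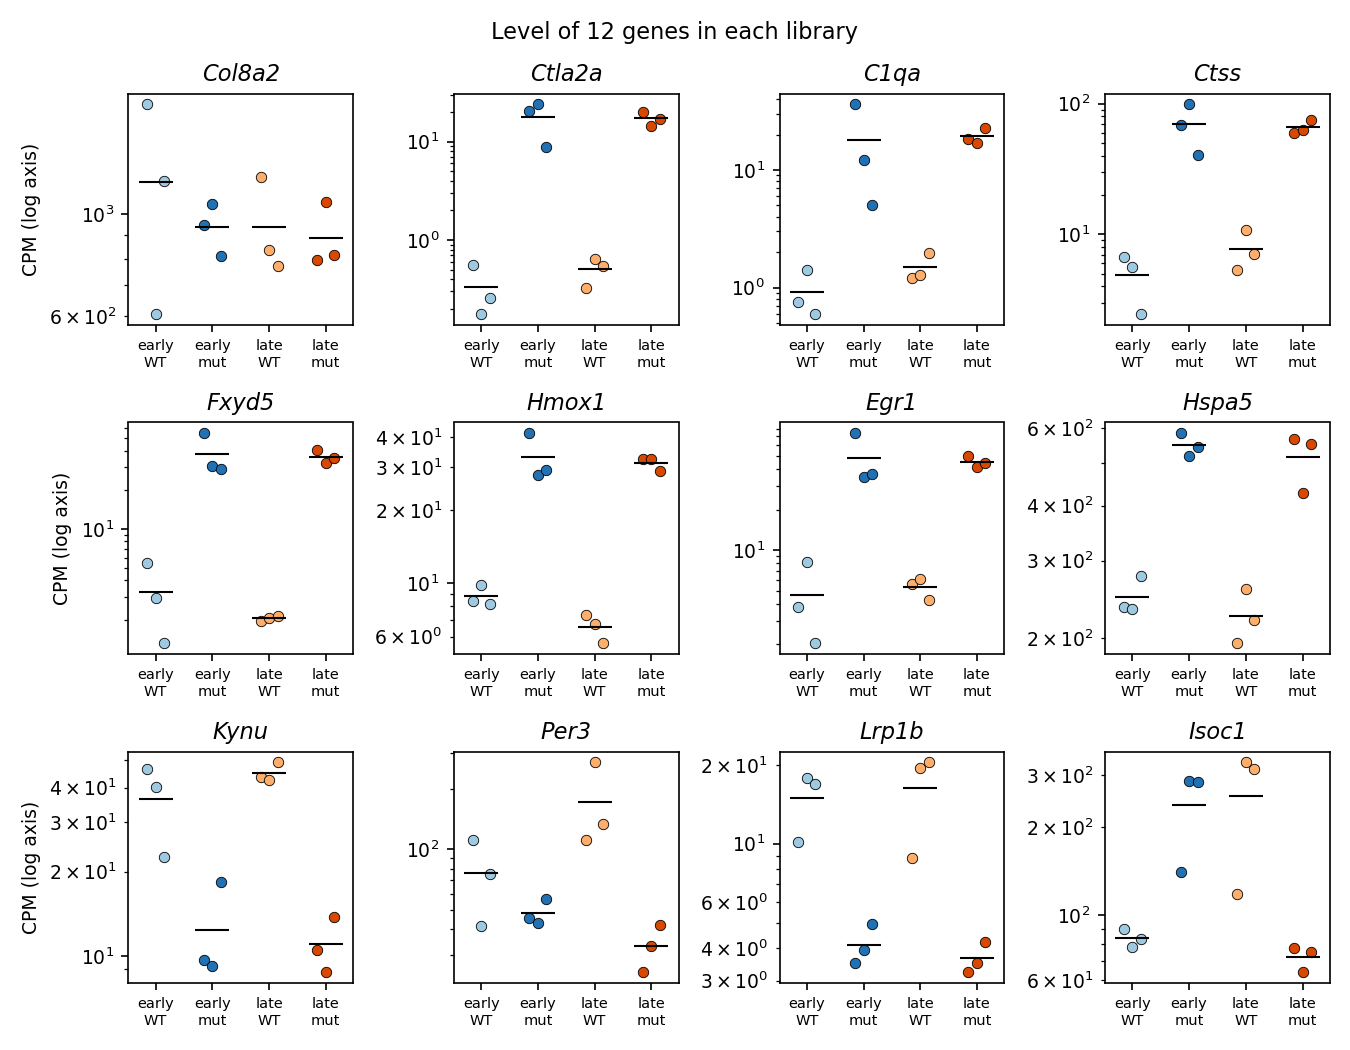
CPM of 12 genes in each library on log axes, with 3 points per group and a line at the group mean. Ctla2a, C1qa, Ctss, Fxyd5, Hmox1, Egr1 and Hspa5 lie higher in mutants at both stages, Col8a2 overlaps between genotypes, and Isoc1 lies higher in early mutants (237 CPM) and lower in late mutants (71.9 CPM) than in wild type of the same stage (83.3 and 255 CPM).

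Among 44 gene lists fixed before the data were examined, 25 moved up and 1 down early by camera with a preset correlation of 0.01, and 16 passed with an estimated correlation. In the macrophage and myeloid list 8 of 21 tested genes rose (11 when adjusted over the list alone), with a median log2 fold change of 1.55, Lyz2 10.5-fold and Ctss 14.2-fold higher. In the immediate early list 5 of 24 rose (11 adjusted over the list alone), among them Jun 3.04-fold, Klf6 3.66-fold and Atf3 9.72-fold higher. These genes respond within minutes to handling of tissue as well as to signals in life. In the unfolded protein response list 3 of 38 rose (12 adjusted over the list alone), Hspa5, Dnajb9 at 2.59-fold and Chac1 at 5.05-fold. The integrated stress response list had 3 of 26 higher (6 adjusted over the list alone), and all 26 of its log2 fold changes lay above 0, with Cebpb at 11.9-fold and Fgf21 at 4.04-fold. Of 35 antioxidant genes 3 rose (4 adjusted over the list alone), Hmox1, the secreted Sod3 at 2.49-fold and Gpx3 at 8.95-fold. In the list of interstitial matrix and remodelling 3 of 35 rose (12 higher and 2 lower adjusted over the list alone), namely Mmp3 at 10.1-fold, Timp1 at 6.29-fold and Col5a1 at 2.27-fold. In the cytokine and chemokine list 3 of 25 rose (8 adjusted over the list alone), with the adhesion molecule Icam1 at 3.72-fold. Complement had 4 of 20 genes higher (7 adjusted over the list alone), and antigen presentation 3 of 20 (6 adjusted over the list alone). Senescence and p53 targets had no gene past the threshold over all genes, 5 adjusted over the list alone, and 23 of 26 log2 fold changes above 0 (median 0.5, adjusted p = 0.012 with an estimated correlation). The endothelial to mesenchymal transition list also had none over all genes and 3 adjusted over the list alone (median 0.22, adjusted p = 0.032 with an estimated correlation).

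Markers of other eye tissues moved with genotype in the same early libraries. In the photoreceptor list 3 of 20 genes rose (12 adjusted over the list alone) and all 20 log2 fold changes lay above 0 (median 2.04). In the keratocyte list, keratocytes being the cells of the corneal stroma, 5 of 20 rose (10 adjusted over the list alone), with Kera 5.38-fold and Lum 4.68-fold higher. In the trabecular meshwork list 2 of 9 rose (6 adjusted over the list alone), Mgp 4.04-fold and Chil1 6.59-fold. Of 15 melanocyte genes none passed over all genes and 5 passed adjusted over the list alone (median 1.96, adjusted p = 0.054 with an estimated correlation). The lens list had a median of -1.34 with no gene past the threshold (adjusted p = 0.26 with an estimated correlation), and of -0.41 without early wild-type replicate 2 and late wild-type replicate 1. Corneal endothelial markers had no gene past the threshold over all genes, 2 adjusted over the list alone, and a median of -0.03 while the test pointed up (adjusted p = 0.27 with an estimated correlation). In the glycolysis list 20 of 21 log2 fold changes lay above 0 with no gene past the threshold (3 adjusted over the list alone, adjusted p = 0.066 with an estimated correlation).

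The late comparison asked the same of animals of at least 8 months. Myeloid and complement genes, immediate early genes, genes of the unfolded protein and integrated stress responses, matrix genes and cell cycle genes were higher in late mutants, and the genes lower in late mutants included the clock gene Per3 and the sodium pump subunit Atp1b1. C1qa and C1qc rose 13-fold and 12-fold, and Lyz2, lysozyme of macrophages, rose 8.16-fold (253 ± 21.7 against 31 ± 6.63 CPM). Hspa5 rose 2.29-fold (515 ± 75.2 against 224 ± 31.8 CPM) and Cdkn1a, the p21 inhibitor of cell division, 4.63-fold (77.9 ± 10.2 against 16.8 ± 6.79 CPM). Per3, a clock gene, was 5.19-fold lower (33.1 ± 8.74 against 172 ± 86.5 CPM), and Atp1b1, the beta subunit of the sodium pump, 1.96-fold lower (740 ± 37.5 against 1450 ± 429 CPM, adjusted p = 0.035). The call of Atp1b1 was lost in 11 of 23 alternatives, among them leaving out any 1 mutant library of either stage or late wild-type replicate 2 or 3, and the late call of Ddit3 in 9 of 23.

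Of the genes selected by size, Bpifa2 was 54.1-fold higher (5.28 ± 0.647 against 0.0874 ± 0.151 CPM), Elobl 38.8-fold, Ctla2a 34.3-fold, Ccnd1 18.7-fold, Cgref1 17.7-fold and Fxyd5 17.6-fold. Derl3, of the degradation machinery of the endoplasmic reticulum, was 11.8-fold and the stress-induced transcription factor Atf3 11.3-fold higher. In the lower direction Kctd14 was 9.67-fold lower, Zfp691 8.14-fold, and Nrtn, the growth factor neurturin, 6.52-fold (3.5 ± 0.158 against 22.9 ± 5.77 CPM). Abcc8, a subunit of ATP-sensitive potassium channels, was 5.88-fold lower, Marf1 5.79-fold, Sfxn5 5.42-fold, Amt, of the glycine cleavage system, 5.2-fold, Tnfsf13os 5.09-fold and Ano5 4.89-fold. Amt lost its call in 6 of 23 alternatives, Kctd14 in 5, Marf1 and Ano5 in 4, Elobl and Cdkn1a in 3 and Sfxn5 in 2, mostly when 1 late library was left out. Marf1 spread widely in wild type (7.16 ± 3.59 against 41.6 ± 35.6 CPM), and without late wild-type replicate 2 the log2 fold changes of Marf1 and Amt were -1.57 and -1.79. In late wild type Zfp691 was at 6.3 CPM in replicate 1 against 36.4 and 24 in replicates 2 and 3. Sfxn5 was at 18.16 against 87.28 and 72.85 CPM, and Amt at 19.15 against 101.6 and 61.62 CPM. Early wild-type replicate 1 lay above the other early wild-type libraries for Zfp691, Sfxn5 and Amt. That of Ano5 was -3.04 without late mutant replicate 2, and Bpifa2 had no reads in late wild type other than in replicate 1. Of the fixed panel, Hmox1 rose 4.74-fold, Ptgs2 3.74-fold and Ddit3, the CHOP transcription factor, 1.98-fold (adjusted p = 0.036). Fn1 was at 484 ± 76.5 against 244 ± 26.8 CPM (adjusted p = 0.062). Col8a1, Slc4a11, Tcf4, Zeb1, Tjp1, Cdh2 and Nqo1 did not pass (adjusted p from 0.108 to 0.73), nor did Dram1, at 0.69 ± 0.35 CPM in mutants and near 0 in wild type (adjusted p = 0.059).

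By the same test 497 genes were higher and 486 lower in late mutants, 460 and 441 of them by at least 2-fold, and 952 of the 983 had no overlap between genotypes, against 25.9% of all tested genes. The count rested on single libraries. It was 3909 without late wild-type replicate 1, and 229, 619 and 238 without late mutant replicates 1, 2 and 3. It was 306 and 364 without late wild-type replicates 2 and 3, and 578 without early mutant replicate 3. Late wild-type replicate 1 differed from replicates 2 and 3 by 273.6 and 273.5 times the sampling noise, against 67.3 between those 2. Its mean correlation within the group (0.905) was close to theirs (0.906 and 0.908). Which late wild-type library is the odd one is therefore not settled, and 3909 is not shown to be the truer count. DESeq2's Wald test gave 2478 genes, and limma-voom gave 1728, of which 33.8% were higher against 50.6% here.

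In the late lists 23 moved up and 3 down with the preset correlation, and 12 passed with an estimated correlation. The myeloid list had 14 of 21 genes higher (17 adjusted over the list alone) and a median log2 fold change of 2.83. Complement had 9 of 20 higher (13 adjusted over the list alone), with C1qb 5.89-fold and C4b 3.53-fold. The unfolded protein response had 13 of 38 higher (23 adjusted over the list alone), including the calcium-binding chaperone Calr at 2.72-fold and Ppp1r15a at 2.96-fold. The integrated stress response had 9 of 26 higher (14 adjusted over the list alone), including Asns at 3.25-fold and Chac1 at 6.3-fold. Immediate early genes had 10 of 24 higher (17 adjusted over the list alone), Egr1 at 8.51-fold and Junb at 5.04-fold. Senescence and p53 targets had 8 of 26 higher (15 adjusted over the list alone), with Phlda3 at 2.53-fold and Igfbp3 at 9.93-fold. Interstitial matrix genes had 11 of 35 higher and 1 lower (20 and 1 adjusted over the list alone), with Timp1 at 6.25-fold, Timp2 at 2.8-fold and Mmp14 at 2.73-fold. The cytokine and chemokine list had 8 of 25 higher (15 higher and 1 lower adjusted over the list alone), with Icam1 at 4.25-fold. The endothelial to mesenchymal transition list had 3 of 28 higher (12 adjusted over the list alone), with S100a4 at 3.83-fold and Tgfb3 at 2.38-fold. In the cell cycle list 7 of 29 rose (16 adjusted over the list alone), led by Ccnd1 and Ccnd2 (7.09-fold), and Cdk1, the mitotic kinase, was at 4.48 ± 0.29 against 0.0648 ± 0.112 CPM.

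The antioxidant list did not pass late (adjusted p = 0.17 with the preset correlation; 5 of 35 higher and 2 lower, 6 and 6 adjusted over the list alone), nor did the glycolysis list (adjusted p = 0.97; 8 of 21 log2 fold changes above 0, median -0.09, 2 higher and 2 lower adjusted over the list alone). Several other late lists passed with the preset correlation alone. In the list of 57 nuclear oxidative phosphorylation subunits no gene passed the threshold, also when adjusted over the list alone, and 8 log2 fold changes lay above 0 (median -0.62, adjusted p = 0.32 with an estimated correlation). Of 13 mitochondrially encoded mRNAs none passed over all genes and 5 were lower adjusted over the list alone (median -0.69, adjusted p = 0.21 with an estimated correlation). Of 18 clock genes Per3 and Per2 were lower and Nfil3, a clock-controlled repressor, higher (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.12 with an estimated correlation). The Descemet and basement membrane list had 5 of 29 genes higher (8 adjusted over the list alone, adjusted p = 0.28 with an estimated correlation), among them Sparc at 2.16-fold, Clu at 1.87-fold and Lamb1 at 2.98-fold. Antigen presentation had 6 of 20 higher (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.12 with an estimated correlation), with the class II genes H2-Aa at 5.15-fold and Cd74 at 4.04-fold. Corneal endothelial markers did not pass as a list (median -0.63, 2 higher and 7 lower adjusted over the list alone); Slc16a1 was 2.55-fold higher, and Cdh4, Ptgds and Atp1b1 were lower at log2 fold changes of -2.17, -1.37 and -0.97. The neural crest list did not pass either (adjusted p = 0.18 with the preset correlation); in it Tfap2b, Eya2 and Rarb were lower at log2 fold changes of -1.07, -1.19 and -1.28. Markers of other cell types moved here too. Of 20 keratocyte genes 7 were higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 0.025 with an estimated correlation), with Kera at 5.1-fold, and of 9 trabecular meshwork genes 4 were higher (4 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). Of 10 lymphocyte and neutrophil genes 2 were higher (4 adjusted over the list alone, median 2.47, adjusted p = 0.15 with an estimated correlation). Of 20 photoreceptor and neuron genes 1 was lower (5 higher and 1 lower adjusted over the list alone, median 1.18, adjusted p = 0.42 with an estimated correlation). The lens list had 4 of 19 genes higher late (7 higher and 4 lower adjusted over the list alone, median 1.38) and did not pass (adjusted p = 0.056 with the preset correlation). The vascular endothelium list had a median of 1.33 with no gene past the threshold (2 adjusted over the list alone, adjusted p = 0.28 with an estimated correlation).

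**Figure D2:**
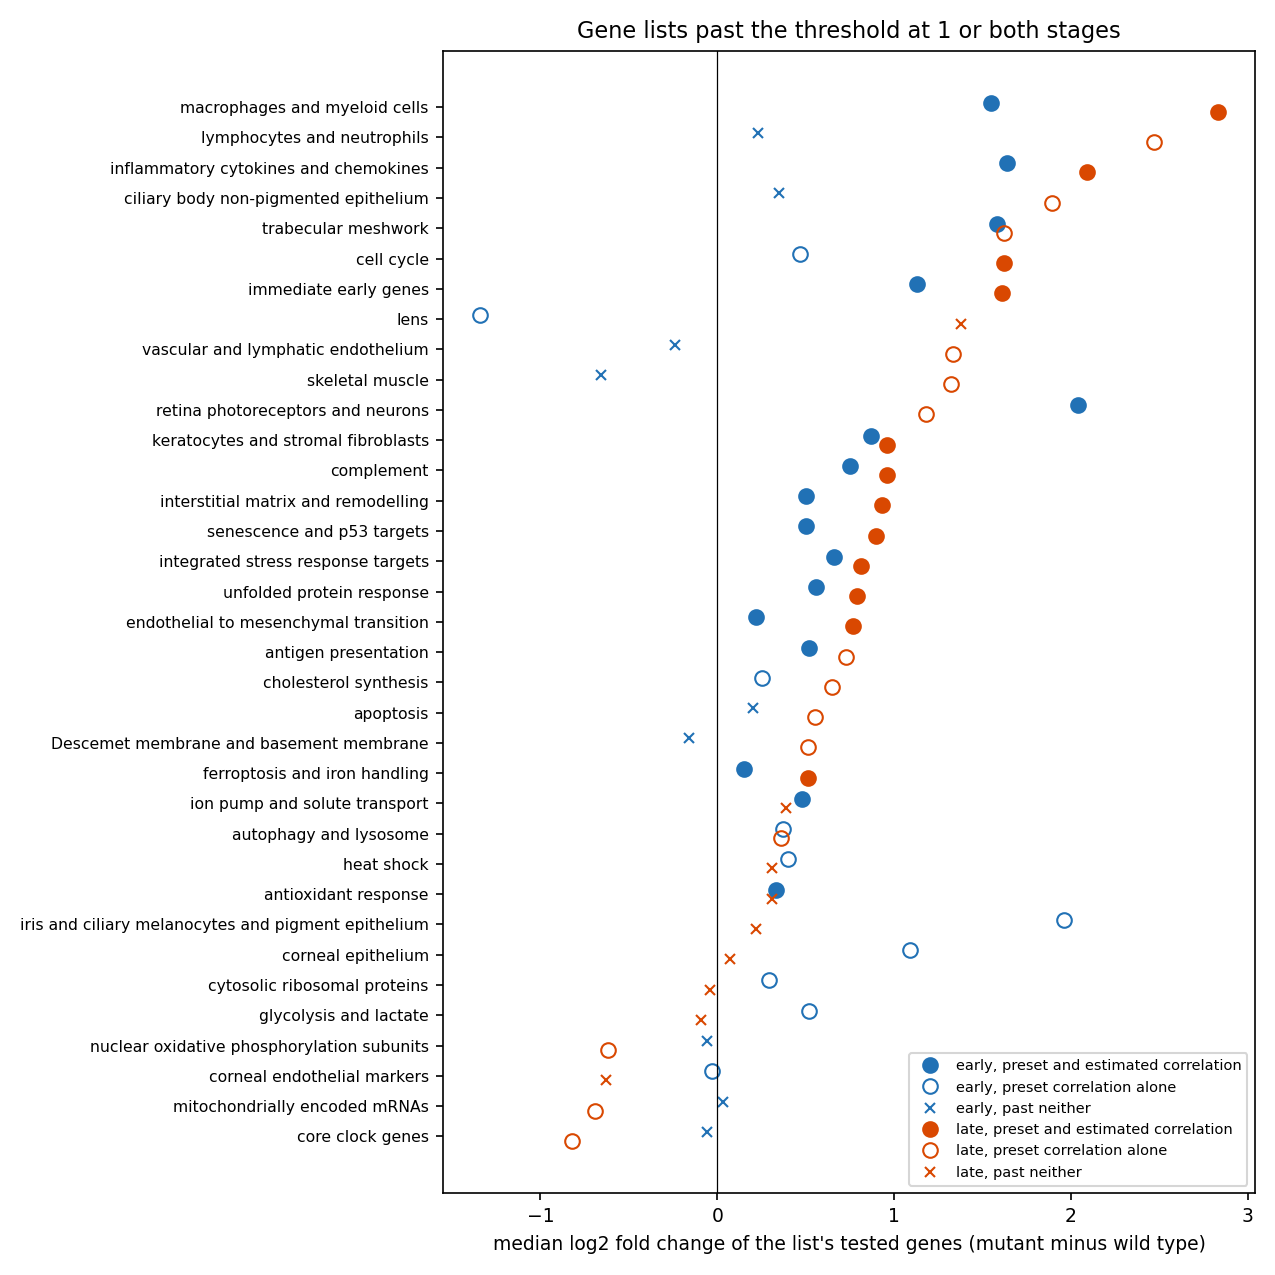
Median log2 fold change of each gene list past the threshold at 1 or both stages, mutant minus wild type, early in blue and late in orange. Filled points passed with the preset and an estimated correlation, open points with the preset correlation alone, and crosses with neither; the myeloid list lies at 1.55 early and 2.83 late.

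Annotation terms carried by the deposited tables gave 49 terms enriched among genes higher early and none among those lower (4 lower genes carried a term), and 156 and 3 terms late. The 5 early terms with the smallest p were, in this order, collagen-containing extracellular matrix (15 genes against 1.68 expected, adjusted p = 9.6e-07), Staphylococcus aureus infection (8 against 0.332), immune system process (16 against 2.68), presentation of exogenous peptide antigen via MHC class II (5 against 0.0958) and systemic lupus erythematosus (7 against 0.396). Late they were collagen-containing extracellular matrix (44 against 8.12), Staphylococcus aureus infection (20 against 1.6), external side of plasma membrane (42 against 9.23), immune system process (50 against 13) and phagosome (26 against 4.04). Among genes lower late the 3 terms were negative regulation of DNA-templated transcription (28 against 12.7, adjusted p = 0.0084), nuclear receptor binding (7 against 1.26) and xenobiotic metabolism by cytochrome P450 (6 against 1.12). The 49 early terms became 12 without early mutant replicate 1, 28 without early wild-type replicate 1 and 30 without early wild-type replicate 3. The 159 late terms became 72 and 98 without late mutant replicates 1 and 3, and 67 and 57 without late wild-type replicates 2 and 3.

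Genes that differed early nearly all differed late in the same direction. Of the 106 early genes, 96 were also higher late, against 2.77 expected of independent lists, and 6 also lower, against 0.162 expected. The 4 remaining genes included, named after their values were seen, Cox6a2, a muscle form of a cytochrome oxidase subunit, and the rod photoreceptor genes Pde6b and Prph2, with late log2 fold changes of 1.84, 2.15 and 1.34 (late adjusted p from 0.052 to 0.315). The number shared was 48 without early mutant replicate 1, 68 without early mutant replicate 2, 67 without early wild-type replicate 1 and 222 with no low-count filter. The 102 shared genes included Ctla2a, C1qa, Ctss, Hmox1, Egr1, Timp1 and Kera. Of the 983 late genes, 76.1% had the same sign early, against 59.2% of all tested genes. Across all tested genes, which are not independent replicates, Pearson's r of the fold changes was 0.18 and Spearman's rho 0.22. The stages share no library, but both comparisons come from 1 fit with a shared estimate of each gene's spread. The 2 lists are therefore not independent, and the expected numbers may be too low. Whether the counts were adjusted between stages is not given in the sources used here, and such an adjustment would bear on this overlap. The 100 genes higher early had nearly the same mean in early and late mutants, with a median log2 ratio of 0.09 and a spread (median absolute deviation) of 0.05, while single early mutant libraries spread by 0.37 to 0.55 around their own mean. The other 9 splits of the 6 mutant libraries gave spreads of 0.22 to 0.4 for these genes. In wild type the stage split had a spread of 0.38 and the other 9 splits 0.39 to 0.65.

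**Figure D3:**
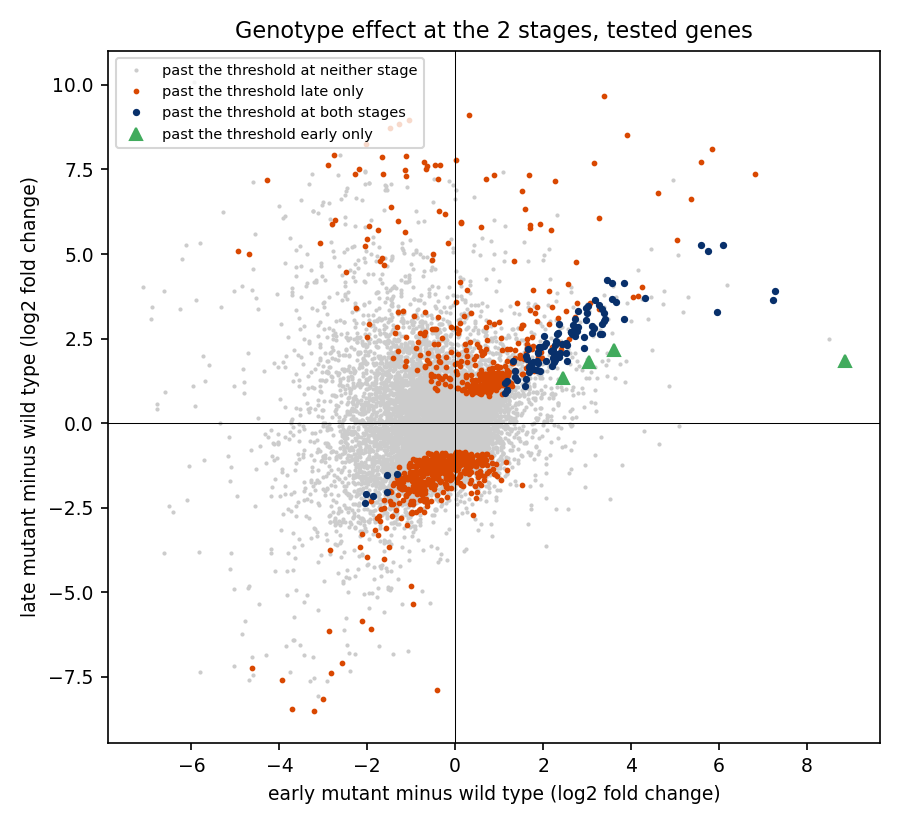
Log2 fold change of each tested gene early (horizontal) and late (vertical), mutant minus wild type. The 102 genes past the threshold at both stages lie in the upper right and lower left, and the 881 past it late only spread over smaller early values.

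**Figure D4:**
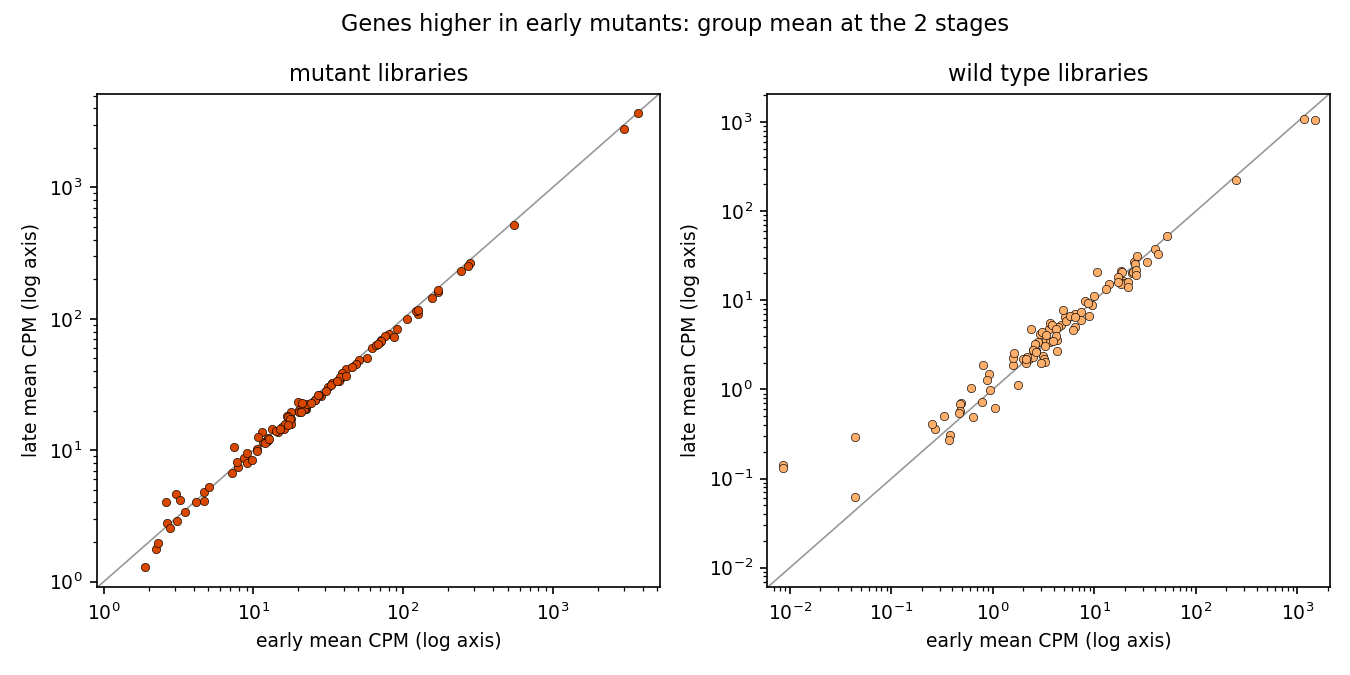
Group mean CPM on log axes at the early and the late stage for the 100 genes higher in early mutants, with a line at equal means. The mutant means lie along the line (spread 0.05 on the log2 scale) and the wild-type means scatter around it (spread 0.38).

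The interaction asked whether the genotype effect differs between stages, and 1 gene passed. Isoc1, an isochorismatase-domain gene, was at 237 ± 83.2 CPM in early mutants against 83.3 ± 5.87 in early wild type, and at 71.9 ± 7.05 in late mutants against 255 ± 119 in late wild type. The difference of the log2 fold changes was -3.33 ± 0.49 (SE, adjusted p = 0.03 by edgeR's quasi-likelihood test), and 2013 genes had an unadjusted p under 0.05. No gene passed with DESeq2 size factors, 327 passed by DESeq2's Wald test, 91 by limma-voom, 28 without early wild-type replicate 1 and 199 without late wild-type replicate 1, and none passed without any 1 of the other libraries except early mutant replicate 1. Of the lists, 18 passed with the preset correlation and none with an estimated one; the cell cycle list had a median difference of 1.31 and the lens list of 2.97 (adjusted p = 0.46 for both with an estimated correlation). Atp1b1 had a difference of -1.37 ± 0.36 (adjusted p = 0.15), so its late decrease was not shown to differ from the early value.

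Late against early, no gene passed by edgeR's quasi-likelihood test in wild type (724 genes at an unadjusted p under 0.05) or in mutants (1174 genes). DESeq2's Wald test gave 1 and 13 genes and limma-voom 0 and 299. Averaged over genotypes, 43 of the 17965 genes had an unadjusted p under 0.05 for the stage difference, where 898 are expected of uniform p-values, and 1098 did when early wild-type replicate 2 and late wild-type replicate 1 were left out. The stage differences in wild type and in mutants ran opposite across genes (Pearson's r -0.46). In mutants 19.3% of tested genes did not overlap between stages, above the share that chance gives, and in wild type 4.7%, below it. These comparisons therefore do not show that the tissue is alike at both ages.

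Early wild-type replicate 2 had at least 1 read in 31527 genes, against 19317 to 23208 in the other 11 libraries, at the lowest depth of all.

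**Figure D5:**
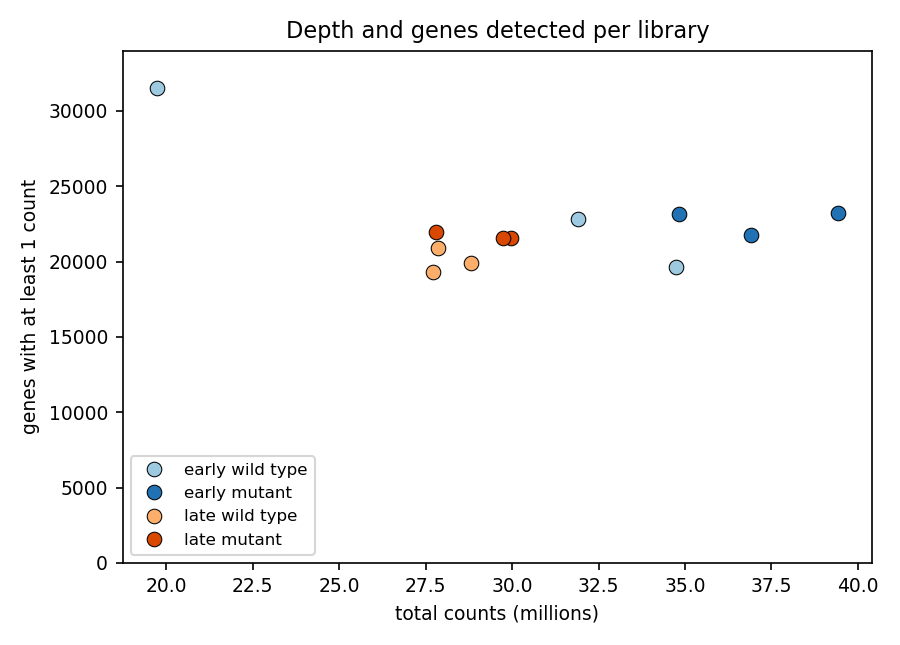
Genes with at least 1 count against total counts per library. Early wild-type replicate 2 stands apart with 31527 genes at 19722598 counts.

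In the authors' deposited tables of protein-coding genes, 269 genes were higher and 62 lower early at a q-value under 0.05, and 588 were higher and 677 lower late. Among genes in both the authors' deposited table and the genes tested here, 102 passed in both early, 220 in the table alone and 1 here alone, and late 835 passed in both, 420 in the table alone and 54 here alone.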

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

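The tests of the detection pattern and of the closeness of the stages, including the 4 scalings and the counts without 2 libraries, were chosen only after these patterns were seen; the counts of other splits were planned.

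Isoc1 was the 1 gene whose genotype effect differed between stages by the test of the difference itself, with a log2 difference of -3.33 ± 0.49 (SE). This call was lost in 11 of 22 alternatives. The early genotype effect of Isoc1 did not pass by itself (adjusted p = 0.0536 by edgeR's quasi-likelihood test). Late wild-type replicate 1 was at 117.6 CPM, against 332.7 and 314 in replicates 2 and 3. Of 60 regroupings drawn from 200, 7 gave at least 1 gene, the real one included, so chance is not excluded for this count. The highest other regrouping gave 1230 genes; it exchanges the genotype labels at 1 stage only, so it measures the mean genotype effect, and points to that structure of the samples.

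Reads in nearly all genes were seen in early wild-type replicate 2 alone, with 3315 genes that had no read in the other 11 libraries. Of 782 olfactory and vomeronasal receptor genes 92.1% had reads there, against 2.4% to 10.9% in the others. Of the 782, 484 had reads in this library alone and are in the table only through it, since genes with no read in any library are absent. The high share is therefore partly fixed by the table. The 3315 genes argue against spill-over from the other libraries. Among the 484 receptor genes the highest count was 51 against a median of 4, or 12.8 times the median. This cannot decide on RNA of 1 other tissue. The limit was set after the pattern was seen, and a tissue with reads in many receptor genes would give no outliers. Genomic DNA was tested by its prediction that counts of silent receptor genes rise with length. No rise was found (Spearman's rho 0.03, one-sided permutation p = 0.25, against 0.08 to 0.25 simulated). This argues against genomic DNA only weakly, because the lengths differ little (quartiles 936 and 1077 bases). The simulated counts could also be 0, while a silent receptor gene is in the table only with a read here. Over all 3315 genes, looked at only after that result, rho was 0.2, as genomic DNA or longer transcripts would give; the source therefore stays open, and no biological explanation was tested.

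Early and late means averaged over genotypes lay close together. For late against early averaged over genotypes, 43 genes, or 0.24% of those tested, had an unadjusted p under 0.05, the highest of 4 forms of this test (25 to 43), against 5.67% in simulated libraries with equal stages and 0.16% in libraries shifted by stage and then adjusted. At most 2 of all splits into 6 and 6 libraries gave means as close as the stages over 4 scalings, which argues against chance. The stage split balances the genotypes. Splits that do not balance them carry part of the genotype effect and could hardly be as close, so the share of close splits is understated. The stage split had the lowest spread with raw counts and plain CPM (0.129 against 0.137 for the next), but not with TMM (0.145 against 0.142) or DESeq2 size factors (0.147 against 0.141). An adjustment of the counts to equal stage means before deposit may account for this, though 64.3% of real p-values were over 0.5 against 94.7% in the adjusted simulation and no source used here names such a step. On this averaged test, stages that do not differ cannot be told apart from an adjustment. The share rose to 6.11% without early wild-type replicate 2 and late wild-type replicate 1, which an adjustment and a spread inflated by these libraries would both give. The mutant libraries, which include neither, argue against unadjusted stages that merely do not differ, for the 100 genes higher early. Their stage means spread by 0.05, against 0.22 to 0.4 in the other splits and at least 0.18 for single libraries around their group mean. Only 10 such splits exist, too few for a share under 0.05.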

How the results depend on the processing

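The gene length and GC content offsets and the fit without both early wild-type replicate 2 and late wild-type replicate 1 were chosen only after the data were seen. No result past the threshold reversed its direction under any alternative run; the log2 fold change of Col8a2, which did not pass, turned positive early without early wild-type replicate 1 and late without late wild-type replicate 1. Of 83 named-gene results 54, and of 88 list results 41, kept their side of the threshold in every setting, an estimated correlation and fry included for lists; the others were lost in 112 and 67 cases and gained in 26 and 77. With no low-count filter the counts were 361 genes early, 1507 late, 297 for the interaction, 67 and 53 between stages in wild type and mutants, 222 shared between stages and 379 terms. With DESeq2's Wald test they were 237, 2478, 327, 1, 13, 202 and 369. Limma-voom gave 1728 genes late, 91 for the interaction and 299 between stages in mutants. Fits of the compared libraries alone gave 489 late, and DESeq2 size factors 0 for the interaction. With the replicate block, for numbers that do not pair the samples, the counts were 106 early, 456 late and 2 for the interaction, neither of them Isoc1 (adjusted p = 0.053). An estimated correlation left 16 lists early and 12 late. Without early wild-type replicate 2 and late wild-type replicate 1 together, 4371 genes passed late, 86 for the interaction and 316 terms. The cause was not tested for any of these. Leaving out each library in turn gave 51 to 179 genes early, 229 to 3909 late, 0 to 199 for the interaction, 0 to 0 between stages in wild type and in mutants, 25 to 28 lists early and 20 to 31 late, 48 to 150 shared genes, 116 to 282 terms, log2 fold changes of Col8a2 of -0.62 to 0.09 early and -0.19 to 0.28 late, and 28 to 35 named genes. The highest late count came without late wild-type replicate 1, and 951 of the 983 genes were among its 3909. At this depth and spread most 2-fold changes go undetected.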

Other observations

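The tests of the myeloid pattern were chosen only after its list medians were seen; the test of genes near Col8a2 and the counts of other splits were planned.

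Further gene groups are given here. Of 37 autophagy and lysosome genes 6 rose late (9 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation), with the proteases Ctsd at 2.36-fold and Ctsl at 2.23-fold, and Gpnmb, a membrane glycoprotein of lysosome-rich cells, at 3.8-fold. Of 22 ferroptosis and iron-handling genes 2 rose early (2 adjusted over the list alone) and 3 late (6 higher and 1 lower adjusted over the list alone), with Slc7a11, the cystine importer, at 5.18-fold. The cholesterol list moved up late (median 0.65, 19 of 24 log2 fold changes above 0, 2 genes higher and 1 lower, 4 and 2 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation), with Msmo1 2.15-fold higher and Insig1 lower at a log2 fold change of -1.65. The ion pump and transport list moved up early (median 0.48, 24 of 31 log2 fold changes above 0, adjusted p = 0.0098 with an estimated correlation) with no gene past the threshold and 3 adjusted over the list alone. Late it did not pass (adjusted p = 0.12 with the preset correlation; 3 higher and 1 lower, 5 and 4 adjusted over the list alone), though Car12, a carbonic anhydrase, was 3.48-fold and the chloride channel Ano1 15.2-fold higher and Atp1b1 lower. Mfn1 and Ppargc1a, which serve mitochondrial fusion and biogenesis, were lower late at log2 fold changes of -1.4 and -1.5, in a list that did not pass as a whole.

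Myeloid genes were higher in mutants at both stages. A lower share of endothelium alone would raise the markers of the other cell types alike. The 95% limits used here resample the genes of a list, not the libraries, so they leave out the spread between replicates. At least 8 early and 12 late of the 15 marker lists had an upper limit below the highest lower limit of any list, with all libraries and without early wild-type replicate 2 and late wild-type replicate 1. Early with all libraries that limit was the melanocytes' (1.61), and only 2 lists lay below the myeloid one (0.36). By these limits the lists did not move alike. This cannot decide on a lower share, since carried-over tissues may differ between libraries. Without these wild-type libraries, the early lens median was -0.41 (upper limit 0.01) against 2.03 for melanocytes (lower limit 1.33) and 2.5 for the myeloid list. Endothelial markers had a late median of -0.63 with all libraries, but did not pass as a list, and 6 of 19 log2 fold changes lay above 0. The abundant Slc4a11 and Col8a1 lay 1.65-fold and 1.43-fold higher late without passing the threshold, while Atp1b1 was 1.96-fold lower. A lower share of endothelium may add to the pattern, but these values do not show it. The 2 wild-type libraries alone do not account for the pattern, since without both the myeloid medians were 2.5 and 3. Keratocyte genes of at least 50 CPM had late medians of 0.31 and, without both, 0.57 (upper limits 1.35 and 1.53). This cannot decide on stroma carried over with the sheet, because abundant genes such as Dcn (mean 20700 CPM) may rise little with it. In this set Lum and Angptl7 rose late (log2 fold changes 2.15 and 2.18), Ptgds fell (-1.37) and the others did not pass. Ptgds is also on the list of corneal endothelial markers, so its fall cannot tell stroma from endothelium. In the full keratocyte list 7 of 20 genes were higher late and 1 lower. Early, stroma cannot be told apart either. There the median of 0.51 (0.63 without both) lay above the lower myeloid limit of 0.36 with all libraries though below 1.64 without both. More myeloid cells in the mutant tissue may also account for the myeloid pattern, as a hypothesis that was not tested. Photoreceptor genes that rose in the same early libraries (median 2.04) keep a difference in dissection open.

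Other splits of the 6 libraries were too few for a share under 0.05, with 10 splits for each comparison. The early comparison gave 106 genes against 0 in the highest other split and the late comparison 983 against 0, each as the 1 split with as many. In wild type between stages the real count was 0, so all 10 splits gave as many, and the highest other gave 1591. That split sets early wild-type replicate 1 with late wild-type replicates 2 and 3, which points to a structure of the samples that crosses stage. In mutants the real count and the highest other were 0, so all 10 splits gave as many.

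Of the 50 tested genes nearest to Col8a2 in the reference order, 6% were past the threshold late, against 5.5% of all tested genes (one-sided Fisher's exact p = 0.52), and none early, so an excess of the kind that a segment of the donor strain around the allele would give was not detected and cannot be excluded.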
